A study of Homo sapiens with 30 samples.

How the data were processed

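RNA from MDA-MB-231 cells was sequenced in 30 libraries, 3 for each of 10 groups. Per the labels' protocols, RNA was purified on silica columns that remove genomic DNA, and polyadenylated RNA was turned into libraries with a directional kit. The submitters' processing notes name HISAT2 (a spliced aligner), Picard and HTSeq (a read counter), without versions, and the builds GRCm38, mm10 and hg38, without a role; the cells are human. The annotation release and HTSeq's strand setting are not given in the sources used here. The authors deposited 3 tables of raw gene counts with gene symbols, which hold whole numbers and no normalization: DMSO and UF010 at 10 µM for 24 h; DMSO, YX968, YX968-NC and YX26862 at 50 nM for 6 h; and the same 4 treatments for 24 h. Each column name matched 1 sample label, and 0 columns belonged to no sample. Nothing shows that libraries were pooled.

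The processing affects the values in several ways. A directional library counted with another strand setting mixes antisense with sense reads, so antisense genes are uncertain, as are overlapping genes, readthrough genes and pseudogenes. The 37 mitochondrially encoded rows were all 0 in the 6 h and 24 h tables and held 1140083 counts in the UF010 table, so the tables were not made in the same way and reads from mitochondrial transcripts could have gone to nuclear pseudogenes. The UF010 table listed 56282 symbols and the others 61904. For gene lists and properties, 34132 UF010 symbols were current, 1479 were matched as older symbols and 20671 were left as deposited; in the other tables these were 58650, 273 and 2981. Positions, GC content and longest transcript length came from a human gene annotation on GRCh38.

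Total counts per library ran from 18078951 to 34620339. Within each group the libraries were compared by chi-square over genes with a pooled count of at least 20 in the pair. A floor of 3 counts over a group was used where all its libraries were at 0, and ratios on 1 to 3 counts have a 95% counting interval.

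Tests were run in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr, a quasi-likelihood F-test per gene and Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. The count tables were fitted separately with all their groups, so that 16529, 16715 and 16321 genes were tested and groups shared an estimate of spread within a table (common dispersion 0.00525, 0.0149 and 0.00302). From these fits came 13 comparisons, 7 of a treatment with DMSO and 6 between compounds. Over all tables, 15496 genes were fitted together for 4 tests of whether effects differed, with a DMSO group for each table. Log2 changes have SE from the fitted F and 95% intervals. There were no blocks or covariates.

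The design, the 37 gene lists, the rule for named genes and most other settings were fixed before the data were examined; 3 settings were added afterwards. By the rule, the text named HDAC3 and HDAC8 always. For each treatment against DMSO it named the 7 largest rises and falls and the 4 most abundant genes each way with an absolute log2 change of at least 1, and for each compound difference the 4 largest each way. Such genes had an adjusted p under 0.05, at least 2 CPM in the higher group and groups that did not overlap, which chance gives for 10% of genes with 3 against 3; clone names were passed over. Up to 4 called members of a list, those with the smallest p, were named too, and any other gene is said to have been chosen after its values were seen. A few genes that met the rule are not reported here, and counts of named genes include them.

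Lists were tested with limma 3.58.1, by camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry, with p-values adjusted over the lists of a comparison. Members were counted over all genes tested and adjusted over the list alone. The lists covered chromatin complexes, cell cycle, cell death, metabolic, stress and signalling genes and markers of other breast, stromal, blood and endothelial cells.

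The settings fixed beforehand were DESeq2 1.42.0, median-ratio scaling, library size alone, no low-count filter, a stricter one, an absolute log2 change of at least 1, an adjusted p under 0.01, a fit with only the groups compared, leaving out each library in turn, and for the similarity of effects only genes of at least 10 CPM. The added ones were a correction for GC content and transcript length (a spline with 5 degrees of freedom per library, used as an offset), leaving out the libraries in doubt (YX968-NC replicate 1 at 6 h and DMSO replicate 2 at 24 h), and both together. Similarity of effects was set beside 20 simulations of unchanged groups that shared simulated controls. Each simulated library, DMSO included, was drawn gene by gene around the DMSO mean of its table with the fitted spread.

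Each step was tested on simulated counts with 200 changed genes. For UF010 61.2%, 89.6% and 90.9% of genes changed 1.5, 2 and 4 fold were recovered (14994 genes in the step, 13 unchanged genes called), for YX968 at 6 h 46.3%, 76.1% and 97% (16472 genes, 6 called) and for YX968 at 24 h 74.6%, 88.1% and 93.9% (16078 genes, 10 called). For the test of whether UF010 and YX968 effects differ these were 26.9%, 68.7% and 89.4% (14116 genes, 6 called). The real UF010 comparison called 12399 genes and this test 8837, far more than the 200 changed here. The simulated rates may therefore not hold for those 2 results. For YX968 at 24 h a list moved on purpose was found, 0 unmoved lists were called, and a simulated GC trend gave 3754 calls before the correction and 0 after it (16321 genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.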

Results

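Gene expression was measured by polyadenylated RNA sequencing in MDA-MB-231, an established human triple-negative breast cancer cell line. The 30 libraries formed 10 groups of 3. In 1 count table, cells given UF010, a histone deacetylase (HDAC) inhibitor, at 10 µM for 24 h were set beside cells given DMSO, the solvent. Separate tables for 6 h and for 24 h each held DMSO, YX968, YX26862 and YX968-NC at 50 nM. The series design describes YX968 and YX26862 as PROTACs, molecules that bring a protein to the cell's degradation machinery, directed at HDAC3 and HDAC8, and YX968-NC as their negative control. Total counts per library lay between 26185092 and 34620339 in the UF010 table. They lay between 18078951 and 32683023 in the 6 h table and between 27672559 and 32406278 in the 24 h table. Levels are means of CPM (counts scaled to the library's total times its TMM factor, which evens out composition) ± SD over the 3 libraries of a group (n = 3 throughout), and log2 fold changes are given ± SE with adjusted p-values. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Counting intervals and floors cover counting error only.

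Libraries of a group differed by more than counting noise, and no pair was a duplicate. At 6 h YX968-NC replicate 1, with 18078951 counts, stood apart from replicates 2 and 3 (chi-square per degree of freedom 132 and 79.3, against 14.9 between those), and MALAT1, a nuclear non-coding RNA, read 284.7 CPM in it and 98.94 and 109.9 in the others. At 24 h DMSO replicate 2 stood apart from replicates 1 and 3 (16.7 and 20.6, against 2.2). In the UF010 table DMSO replicate 2 was also further from replicates 1 and 3 (35.2 and 14.3) than those were from each other (6.19), and without it 13194 genes passed with UF010. The deviations of these 3 libraries followed transcript length, with Spearman coefficients across genes of -0.56, -0.53 and -0.52. Their partners had opposite trends, such as 0.59 in YX968-NC replicate 2 at 6 h and 0.49 in DMSO replicate 1 of the UF010 table. Each library is set against the other libraries of its group, so these trends are not independent.

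**Figure D1:**
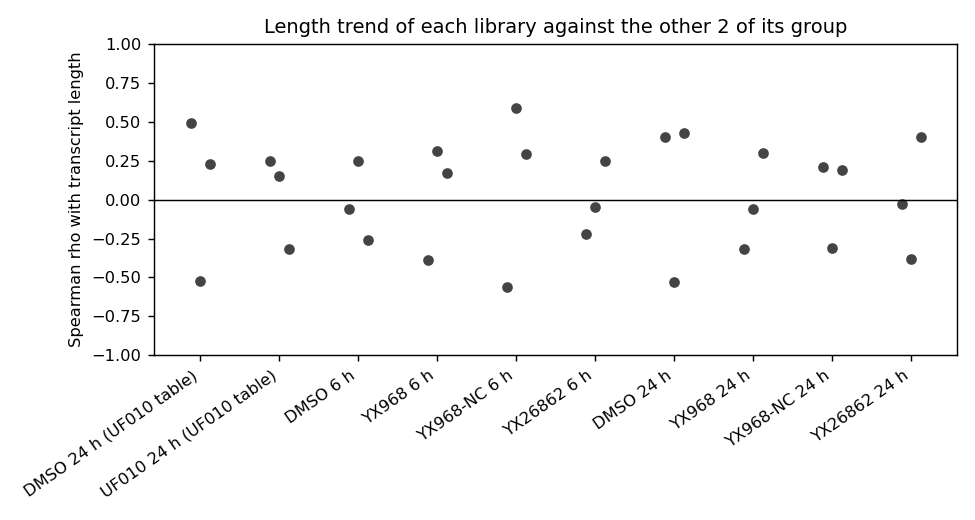
Spearman coefficient, across genes, between transcript length and each library's log ratio to the mean of the other 2 libraries of its group; each point is a library. YX968-NC replicates 1 and 2 at 6 h lie at -0.56 and 0.59, and DMSO replicate 2 lies at -0.53 in the 24 h table and -0.52 in the UF010 table.

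The targeted genes were examined first. A PROTAC acts on the protein, which was not analysed here, so mRNA levels of the targets do not check the labels. HDAC3, a class I deacetylase gene on chromosome 5 (141620876 to 141636870, GRCh38), stood at 90.7 ± 3.14 CPM with YX968 and 91.4 ± 2.79 with DMSO at 6 h, a log2 change of -0.01 ± 0.07 (adjusted p = 0.97). At 24 h its level was 108 ± 3.69 with YX968 and 108 ± 6.8 with DMSO (log2 change 0 ± 0.05, adjusted p = 0.97). HDAC8, on chromosome X (72329516 to 72573199), stood at 8.41 ± 0.337 against 7.85 ± 0.819 CPM at 6 h (0.1 ± 0.16, adjusted p = 0.85) and at 11.3 ± 0.569 against 11.8 ± 0.535 at 24 h (-0.06 ± 0.07, adjusted p = 0.65). With YX26862 at 24 h the changes were -0.05 ± 0.05 for HDAC3 and -0.12 ± 0.07 for HDAC8 (adjusted p = 0.58 and 0.37). With YX968-NC at 6 h HDAC8 was at 11.2 ± 3.17 CPM, and its 3 libraries read 14.7, 8.44 and 10.6 (log2 change 0.5, adjusted p = 0.12). Without YX968-NC replicate 2 the change was 0.67 and passed (adjusted p = 0.01). HDAC8 was then also lower with YX968 and YX26862 than with YX968-NC (-0.57 and -0.48, adjusted p = 0.022 and 0.038), and lower in the YX968-NC effect at 24 h than at 6 h (-0.78, adjusted p = 0.0021). Without replicate 1 none of these passed. UF010 left HDAC3 at 109 ± 5.84 against 101 ± 5.96 CPM (adjusted p = 0.17), while HDAC8 fell from 27.5 ± 0.599 to 23 ± 1.42 CPM (-0.26 ± 0.06, adjusted p = 0.0049). HDAC3 passed without DMSO replicate 2 (0.17, adjusted p = 0.01) and after a correction for GC content and transcript length (0.12, adjusted p = 0.015). With libraries scaled by library size alone the UF010 calls changed places: HDAC3 passed (0.26, adjusted p = 0.0067) and HDAC8 missed (-0.1, adjusted p = 0.22).

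UF010 raised genes that had no counts in the solvent and lowered cell division genes. KCNJ10, a potassium channel gene of glia on chromosome 1 (159998651 to 160070483), had no count in any DMSO library and 5.98 ± 0.598 CPM with UF010, at least 176-fold higher against a floor of 3 counts over the 3 DMSO libraries. By the same measure IL21R, a cytokine receptor gene, was at least 107-fold higher, the calcium channel subunit gene CACNA2D2 at least 85.4-fold, LGI3 at least 71.5-fold and the nuclear receptor gene HNF4A at least 61.9-fold. TMEM63C had 1146 counts with UF010 and 2 with DMSO, a ratio of 569 with a 95% counting interval from 157 to 4710. Among abundant genes, THBS1 (thrombospondin, a matrix protein) rose from 1340 ± 140 to 3760 ± 146 CPM, and ANKRD1 from 566 ± 9.78 to 1620 ± 34.4 CPM (log2 changes 1.49 ± 0.07 and 1.51 ± 0.04, adjusted p = 2.2e-07 and 1.5e-08). CTGF, a matricellular protein gene, rose by 1.18 ± 0.04 (adjusted p = 3e-08).

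The deepest UF010 loss was in SLCO4A1, an organic anion transporter gene on chromosome 20 (62642445 to 62685785), from 139 ± 2.04 to 7.56 ± 1.23 CPM (log2 change -4.21 ± 0.1, adjusted p = 1e-08). EFCAB2 changed by -3.84 ± 0.17, the cytokine gene CSF3 by -3.55 ± 0.12 and the stress transcription factor gene ATF5 by -3.5 ± 0.1. PLK1, a mitotic kinase gene, fell from 196 ± 5.13 to 26.8 ± 2.84 CPM, and the mitotic kinesin gene KIF20A from 162 ± 7.28 to 23.8 ± 3.87 CPM (-2.87 ± 0.08 and -2.78 ± 0.11). PHF19, a Polycomb-associated gene, changed by -2.72 ± 0.06. The most abundant genes to fall were MMP14, a membrane metalloproteinase gene, from 1080 ± 43.3 to 268 ± 26.9 CPM (-2.01 ± 0.07), NUCKS1 (-1.31 ± 0.06), the DNA topoisomerase gene TOP2A (-1.58 ± 0.11) and ANLN, which encodes a cytokinesis protein (-1.58 ± 0.11). Adjusted p-values of these 11 genes were 2.2e-06 or smaller.

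In all, 12399 of 16529 genes tested differed between UF010 and DMSO at an adjusted p under 0.05, 6174 higher and 6225 lower. Their median absolute log2 change was 0.724, and 4455 changed by at least 1, of which 3334 were higher and 1121 lower. Library size alone gave 7410 higher and 4681 lower, with the median of all genes moved by 0.162, so directions are relative to the chosen scaling. The genes named by rule kept their calls under every setting tried.

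**Figure D2:**
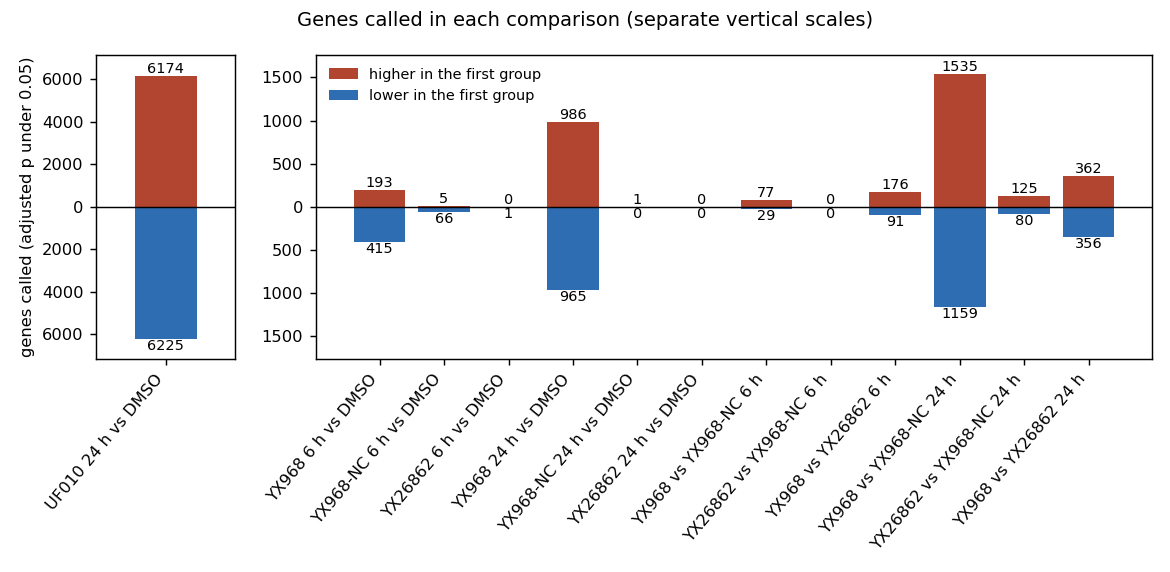
Number of genes called higher (upward bars) and lower (downward bars) in the first group of each comparison at an adjusted p under 0.05. UF010, on its own vertical scale, has 6174 higher and 6225 lower, while YX968 at 24 h has 986 and 965 and YX26862 at 24 h has 0 and 0.

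Cell division lists fell together with UF010. All 38 mitosis genes fell, with a median log2 change of -1.88. CCNB1, the mitotic cyclin gene, changed by -2.25 ± 0.06, the kinase gene AURKA by -1.99 ± 0.05 and the kinetochore gene NDC80 by -2.17 ± 0.06. The mitosis list had adjusted p = 1.1e-35, and adjusted p = 0.2 with an estimated correlation. Of 41 DNA replication genes 40 fell and 1 rose, with a median of -1.25. The leading genes were TYMS (thymidylate synthase, -2.65 ± 0.08), RRM1 (-1.74 ± 0.06) and the helicase subunit gene MCM4 (-1.66 ± 0.06). The replication list had adjusted p = 1.3e-21, and adjusted p = 0.2 with an estimated correlation. Among 30 MYC and ribosome biogenesis genes 26 fell, including UBTF (-1.41 ± 0.06) and NCL (-0.81 ± 0.04). The 1 that rose was MYC itself (0.74 ± 0.05). The MYC list had a median of -0.54, adjusted p = 5.5e-05, and adjusted p = 0.29 with an estimated correlation. Of 27 genes of the SIN3, NuRD and CoREST deacetylase complexes 23 fell and 1 rose, with CHD3 at -1.49 ± 0.06, MTA2 at -1.01 ± 0.05 and RBBP4 at -0.9 ± 0.05. The SIN3, NuRD and CoREST list had a median of -0.48, adjusted p = 0.00044, and adjusted p = 0.15 with an estimated correlation. Cohesin genes fell in 12 of 14 cases, among them RAD21 (-1.02), with a list median of -0.93. The cohesin list had adjusted p = 0.00011, and adjusted p = 0.44 with an estimated correlation. Counts adjusted over the list alone were the same for these 5 lists.

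Neuronal genes, epithelial genes and markers of some other cell types rose with UF010. Luminal breast and endothelial markers did not pass the list test and are given in the last section. Of 25 neuronal genes 19 rose and 1 fell: the granule protein gene SCG2 went from 4.28 to 98.2 CPM (4.51 ± 0.08) and the tau gene MAPT from 1.51 to 62.2 CPM (5.37 ± 0.09). The list median was 2.39, also with the member at 0 in a group set at its bound. The neuronal list had adjusted p = 3.9e-13, and adjusted p = 0.15 with an estimated correlation. Of 28 epithelial genes 20 rose and 4 fell, with MAL2 at 3.83 ± 0.07, SPINT1 at 2.84 ± 0.06 and the tight junction genes TJP3 and CLDN1 at 5.05 ± 0.15 and 1.99 ± 0.06. The epithelial list had a median of 1.33, adjusted p = 1.5e-06, and adjusted p = 0.2 with an estimated correlation. All 8 basal and myoepithelial markers rose, including the smooth muscle gene CNN1, from 0.126 to 11.9 CPM (6.52 ± 0.17), and the keratin gene KRT17 (2.94 ± 0.13). The basal marker list had adjusted p = 1.1e-05, and adjusted p = 0.15 with an estimated correlation. Fibroblast markers rose in 7 of 7 cases, with the collagen gene COL1A1 at 1.66 ± 0.06 and PDGFRB at 2.17 ± 0.09. The fibroblast marker list had adjusted p = 0.0068, and adjusted p = 0.39 with an estimated correlation. Of 7 blood and immune cell markers 4 rose and 1 fell, with CD14 at 2.17 ± 0.09 and LCP1 at 1.17 ± 0.07. The blood marker list had adjusted p = 0.02, and adjusted p = 0.29 with an estimated correlation. Of 17 retinoic acid-responsive genes 12 rose and 2 fell, with the transglutaminase gene TGM2 at 1.62 ± 0.04 and CRABP2 at 2.26 ± 0.07 (median 0.56, also with the member at 0 set at its bound). The retinoic acid list had adjusted p = 0.00028, and adjusted p = 0.29 with an estimated correlation. These counts too were the same when adjusted over the list alone. The low-count filter drops members that are silent in both groups. A member silent in DMSO was therefore tested only if UF010 raised it, which tilts these shares and medians toward rises.

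**Figure D3:**
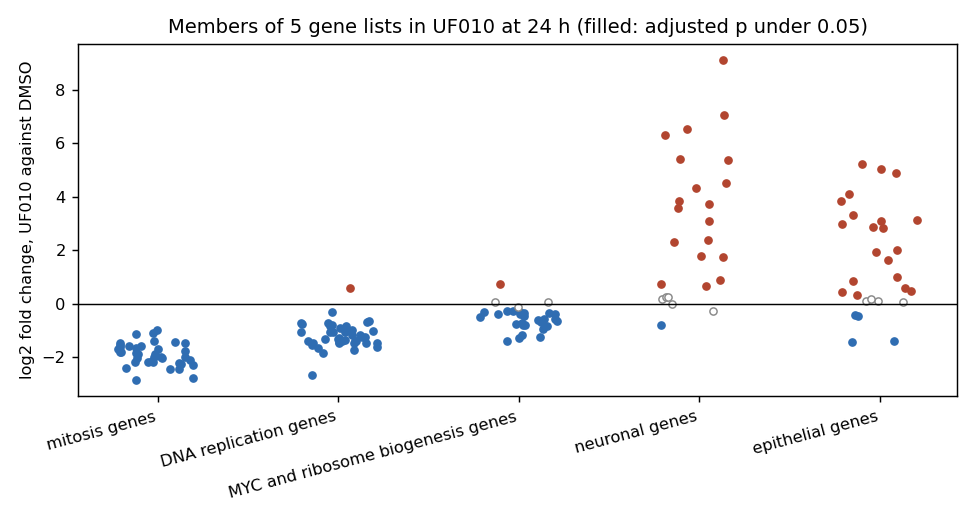
Log2 fold change of UF010 over DMSO at 24 h for each member of 5 gene lists; filled points have an adjusted p under 0.05, open points do not. Medians lie at -1.88 for mitosis genes, -1.25 for DNA replication genes, -0.54 for MYC and ribosome biogenesis genes, 2.39 for neuronal genes and 1.33 for epithelial genes.

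Several lists moved in both directions with UF010 and did not pass the list test. Among 10 deacetylase genes, HDAC11 (1.61 ± 0.11) and HDAC5 (0.33 ± 0.05) rose and 3 fell, among them HDAC7 (-0.99 ± 0.06) and HDAC1 (-0.51 ± 0.04; list adjusted p = 0.78). Of 11 cell cycle inhibitor genes 5 rose, including BTG2 (4.45 ± 0.23) and CDKN1A, the p21 gene (0.93 ± 0.06), and 3 fell, including CDKN2C (-1.45; list adjusted p = 0.51). Interferon-stimulated genes rose in 14 and fell in 21 of 42 cases, with IFIT2 at -2.56 ± 0.08 and IFIT3 at -2.23 ± 0.07 (list adjusted p = 0.15). Apoptosis regulators rose in 9 and fell in 16 of 33 cases, with the death ligand gene TNFSF10 at 1.29 ± 0.06 (list adjusted p = 0.26). Adjusted over the list alone these counts were the same. Over 37 lists, 14 passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.15) and 34 by fry, which asks only whether members move one way on balance.

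YX968 at 6 h raised a small set of genes. ABCA1, the cholesterol exporter gene on chromosome 9 (104781002 to 104928237), rose from 35 ± 4.03 to 118 ± 13.3 CPM (log2 change 1.76 ± 0.26, adjusted p = 0.0052). TBL1XR1, which encodes a subunit of the NCoR/SMRT corepressor complex that holds HDAC3 (chromosome 3, 177019340 to 177228000), rose from 102 ± 3.37 to 250 ± 6.56 CPM (1.29 ± 0.09, adjusted p = 8.6e-05). BMF, a pro-apoptotic gene of the BCL2 family, went from 15.7 ± 0.801 to 37.2 ± 0.538 CPM (1.25 ± 0.13, adjusted p = 0.00058), and PLAU, the urokinase gene, from 362 ± 8.96 to 735 ± 10.7 CPM (1.02 ± 0.06, adjusted p = 2.3e-05). Less abundant genes followed: TNFSF18 (1.12 ± 0.23), the GTPase gene RRAD (1.08 ± 0.2) and the retinaldehyde reductase gene DHRS3 (1.08 ± 0.19), with adjusted p = 0.023, 0.014 and 0.013.

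Mitochondrial pseudogenes of the nuclear genome were among the genes that fell with YX968 at 6 h: MTCO1P12 went from 21.9 ± 0.222 to 6.07 ± 0.829 CPM (-1.85 ± 0.16, adjusted p = 0.00026), MTATP6P1 from 83.3 ± 1.85 to 28.7 ± 5.76 CPM (-1.53 ± 0.19) and MTND2P28 from 50.7 ± 4.64 to 21.3 ± 1.57 CPM (-1.25 ± 0.15). They are near copies of mitochondrial genes, which stood at 0 in every library of the 6 h and 24 h tables, so where their reads came from is uncertain. SOX21, a neural transcription factor gene (chromosome 13, 94709622 to 94712399), fell from 3.26 ± 0.437 to 1.23 ± 0.249 CPM (-1.41 ± 0.18, adjusted p = 0.002). MAMDC4 changed by -1.28 ± 0.12, PABPC1L by -1.06 ± 0.13, WDR97 by -1.27 ± 0.25, the leukotriene receptor gene LTB4R by -1.1 ± 0.1 and the readthrough gene RTEL1-TNFRSF6B by -1.51 ± 0.17. RTEL1-TNFRSF6B shares exons with its parent genes and LTB4R overlaps LTB4R2, so these values are uncertain. Several of the falls were shared. With YX968-NC, MAMDC4, PABPC1L and LTB4R also fell (-0.92, -0.8 and -0.72, edgeR adjusted p = 0.025, 0.038 and 0.025). With YX26862 they stood at -0.87, -0.87 and -0.73 and did not pass (adjusted p = 0.058 each). Without YX968-NC replicate 1 they were lower with all 3 compounds, as were WDR97, RTEL1-TNFRSF6B and MTCO1P12. With all libraries MTATP6P1 and MTND2P28 passed with neither other compound.

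With YX968 at 6 h, 608 of 16715 genes passed, 193 higher and 415 lower, and 91 changed by at least 1 on the log2 scale (11 higher, 80 lower). The higher to lower split was 97 to 898 with library size alone, where the median of all genes moved by -0.104, and 666 to 923 after a correction for GC content and transcript length. Leaving out DMSO replicates 1, 2 and 3 gave 183, 273 and 132 genes, and leaving out YX968 replicates 1, 2 and 3 gave 227, 155 and 123. The same fit without YX968-NC replicate 1, which stood apart from its group, gave 3082 (1520 higher, 1562 lower). Of the 16 named genes, 12 kept their calls under every setting. TNFSF18 lost its call without any library but YX968 replicate 3, WDR97 without any but DMSO replicate 2, RRAD without any but DMSO replicate 1 and YX968 replicate 2, and DHRS3 without DMSO or YX968 replicate 3 (adjusted p up to 0.12, 0.11, 0.072 and 0.085).

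**Figure D4:**
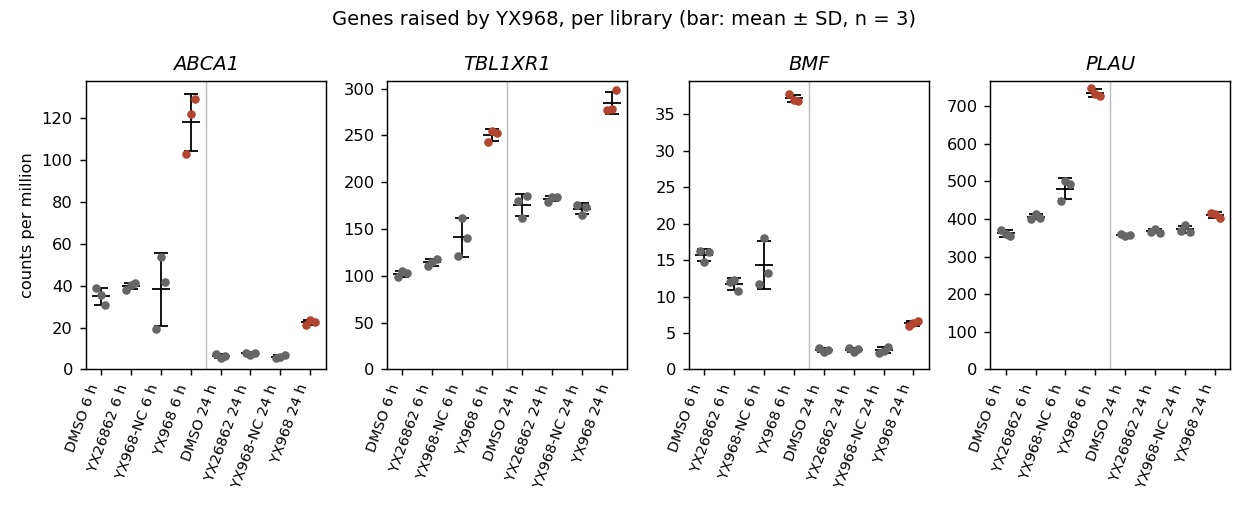
CPM of ABCA1, TBL1XR1, BMF and PLAU in each library at 6 h (left of the grey line) and 24 h (right), with the mean ± SD of each group's 3 libraries; YX968 libraries are red. At 6 h ABCA1 averages 118 with YX968 and 35 with DMSO, and TBL1XR1 averages 250 and 102.

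Among the lists fixed beforehand, 8 of 36 passed with YX968 at 6 h, each with members higher on balance, 0 passed with an estimated correlation (smallest adjusted p = 0.05) and 6 passed by fry. Of 7 NCoR/SMRT genes 2 rose, TBL1XR1 and TBL1X (0.69 ± 0.17), and 3 rose adjusted over the list alone. The NCoR/SMRT list had adjusted p = 4.3e-05, and adjusted p = 0.05 with an estimated correlation. Mesenchymal and matrix genes rose in 7 of 35 cases, 8 adjusted over the list alone, with PLAU, TGFBI (0.34 ± 0.06), THBS1 (0.64 ± 0.12) and CCN1 (0.28 ± 0.06). The mesenchymal list had adjusted p = 2.2e-06, and adjusted p = 0.44 with an estimated correlation. MYC and ribosome biogenesis genes rose in 3 of 30 cases, 6 adjusted over the list alone, and MYC went from 230 to 323 CPM (0.49 ± 0.08). The MYC list had adjusted p = 3.7e-06, and adjusted p = 0.079 with an estimated correlation. Immediate early genes rose in 7 and fell in 1 of 29 cases, 8 and 5 adjusted over the list alone: the MAP kinase phosphatase genes DUSP4, DUSP5 and DUSP1 changed by 0.59 ± 0.06, 0.58 ± 0.06 and 0.76 ± 0.1, while EGR1 changed by -0.6 ± 0.13. The immediate early list had adjusted p = 0.0059, and adjusted p = 0.53 with an estimated correlation. Of 32 NF-kB and inflammatory genes 6 rose and 2 fell, 8 and 3 adjusted over the list alone, with IL1B at 0.63 ± 0.07, IL6 at 0.64 ± 0.1 and IL24 at 0.6 ± 0.11. The NF-kB list had adjusted p = 0.046, and adjusted p = 0.55 with an estimated correlation. Fatty acid and lipid storage genes rose in 3 of 29 cases, 4 adjusted over the list alone: the lipid droplet gene PLIN2 (0.67 ± 0.07), SREBF1 (0.53 ± 0.09) and ANGPTL4 (0.57 ± 0.12). The fatty acid list had adjusted p = 0.0056, and adjusted p = 0.55 with an estimated correlation. With library size alone the medians of the immediate early, NF-kB and fatty acid lists turned to -0.02, -0.09 and -0.01. Of 42 interferon-stimulated genes 3 rose, namely IFIT2 (0.74 ± 0.07), IRF1 (0.45) and IFIT3 (0.46), and the list as a whole did not pass (adjusted p = 0.95); adjusted over the list alone 3 rose and 3 fell.

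At 24 h YX968 again raised ABCA1, from 6.54 ± 0.979 to 22.5 ± 1.18 CPM (1.78 ± 0.1, adjusted p = 5.9e-08), and BMF, from 2.66 ± 0.279 to 6.36 ± 0.338 CPM (1.25 ± 0.12, adjusted p = 2.7e-05). LTBP3, a TGF-beta binding protein gene, rose from 22.6 ± 3.6 to 48 ± 3.58 CPM (1.09 ± 0.1, adjusted p = 2.6e-05). Less abundant genes that rose were MUSK, a receptor kinase gene of the neuromuscular junction (1.58 ± 0.19), SUN3 (1.42 ± 0.18), the antisense gene ZMIZ1-AS1 (1.4 ± 0.18), the epithelial sodium channel gene SCNN1A (1.27 ± 0.17) and the phosphatase gene PTPRH (1.17 ± 0.14). The largest falls were in the non-coding gene LINC00707, from 7.15 ± 0.562 to 2.96 ± 0.251 CPM (-1.27 ± 0.1, adjusted p = 2.8e-06), and CHAC1, a glutathione-degrading stress gene, from 7.6 ± 1.26 to 3.58 ± 0.461 CPM (-1.08 ± 0.16, adjusted p = 0.00066). GPR17 (-0.97 ± 0.1), MYO7B (-0.96 ± 0.09), SOX21 (-0.93 ± 0.13) and JDP2 (-0.89 ± 0.09) followed. The counting's strand setting is not given in the sources used here, so reads of ZMIZ1-AS1 and its sense partner cannot be separated.

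With YX968 at 24 h, 1951 of 16321 genes passed, 986 higher and 965 lower, with a median absolute log2 change of 0.268 among them; 42 changed by at least 1. Library size alone gave 669 higher and 1394 lower. The count was 796 without YX968 replicate 2 and 528 without YX968 replicate 3. With only the 2 groups in the fit it was lower still, as given below under processing. PLCH2 (-0.87 ± 0.25, adjusted p = 0.039) was the 1 of 15 named genes that lost its call, without DMSO replicates 1 or 2 or YX968 replicates 1 or 3 (adjusted p up to 0.13).

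Lipid genes led the lists at 24 h. Of 29 fatty acid and lipid storage genes 11 rose and 3 fell, 14 and 4 adjusted over the list alone: SCD, the fatty acid desaturase gene, went from 123 to 242 CPM (0.98 ± 0.07), PDK4 changed by 0.57 ± 0.07 and ACSL3 by 0.35 ± 0.05. The fatty acid list had adjusted p = 3.6e-05, and adjusted p = 0.19 with an estimated correlation. Hypoxia-inducible genes rose in 7 of 30 cases, 9 adjusted over the list alone, with the glucose transporter gene SLC2A3 at 0.38 ± 0.05 and VEGFA at 0.33 ± 0.05. The hypoxia list had adjusted p = 3e-04, and adjusted p = 0.26 with an estimated correlation. TBL1XR1 (0.69 ± 0.05) and TBL1X (0.36 ± 0.05) were the 2 of 7 NCoR/SMRT genes to rise, also 2 adjusted over the list alone. The NCoR/SMRT list had adjusted p = 0.0012, and adjusted p = 0.19 with an estimated correlation. Of 18 circadian clock genes 4 rose and 1 fell, 6 and 1 adjusted over the list alone, with ARNTL, the BMAL1 gene, up from 14.2 to 24.3 CPM (0.77 ± 0.07), NR1D1 at 0.48 ± 0.07 and CRY2 at -0.25 ± 0.08. The circadian list had adjusted p = 0.0053, and adjusted p = 0.42 with an estimated correlation. Polyadenylated histone genes fell in 4 of 15 cases, 6 adjusted over the list alone, with H2BC12 down from 17 to 10.7 CPM (-0.68 ± 0.07) and H2AC6 at -0.57 ± 0.1. The histone list had adjusted p = 0.0017, and adjusted p = 0.42 with an estimated correlation. Among 9 cell cycle inhibitor genes 2 fell, CDKN1A (-0.34 ± 0.06) and CDKN2C (-0.29 ± 0.07), while adjusted over the list alone 1 rose and 4 fell. The cell cycle inhibitor list had adjusted p = 0.023, and adjusted p = 0.57 with an estimated correlation. Of 38 mitosis genes 6 rose and 1 fell, 9 and 1 adjusted over the list alone, with TOP2A at 0.29 ± 0.07 and CDC20 at -0.16 ± 0.05. The mitosis list had adjusted p = 0.0094, and adjusted p = 0.57 with an estimated correlation. Retinoic acid-responsive genes rose in 5 of 14 cases, with DHRS3 at 1.09 ± 0.15 and TGM2 at 0.3 ± 0.03; adjusted over the list alone 5 rose and 1 fell. The retinoic acid list had adjusted p = 0.018, and adjusted p = 0.42 with an estimated correlation. In all 9 of 36 lists passed, 0 with an estimated correlation (smallest adjusted p = 0.19) and 12 by fry.

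YX968-NC and YX26862 were set against DMSO in the same way. With YX968-NC at 6 h the adhesion gene AMIGO2 rose from 313 ± 21.4 to 442 ± 15.7 CPM (0.5 ± 0.07, adjusted p = 0.025) and PLAU from 362 ± 8.96 to 480 ± 28.7 CPM (0.41 ± 0.06, adjusted p = 0.026), with SOCS2 (0.47 ± 0.08), PDGFC (0.42 ± 0.07) and NUDT21 (0.41 ± 0.07) also higher. GABRE, a GABA receptor subunit gene, fell from 21.5 ± 1.67 to 9.71 ± 2.66 CPM (-1.13 ± 0.16, adjusted p = 0.025) and the junction gene CGN changed by -1.07 ± 0.2. The other falls named by rule, RTEL1-TNFRSF6B (-1.37 ± 0.17), STAG3L5P (-1.23 ± 0.23), PDXDC2P-NPIPB14P (-1.12 ± 0.2), PTOV1-AS2 (-1.04 ± 0.16) and DDX12P (-1.01 ± 0.19), are readthrough, pseudogene or antisense genes with uncertain counts. In all, 71 genes passed, 5 higher and 66 lower, against 609 and 679 by DESeq2, 944 and 634 with no low-count filter, and 55 and 195 after the GC and length correction. The count was 853 without YX968-NC replicate 1, 4416 without its replicate 2, and 0, 11 and 0 without DMSO replicates 1, 2 and 3 (4346 genes had an unadjusted p under 0.05 with all libraries). Each of the 12 named genes lost its call without DMSO replicate 1 or 3, at an adjusted p under 0.01 and with only the 2 groups in the fit. All but AMIGO2 and RTEL1-TNFRSF6B also lost theirs without DMSO replicate 2, and STAG3L5P, CGN and DDX12P without YX968-NC replicate 3 (adjusted p up to 0.44). Of 36 lists 7 passed, led by 48 cytosolic ribosomal protein genes with a median of 0.57, of which 0 were called by edgeR over all genes and 45 rose adjusted over the list alone. The ribosomal protein list had adjusted p = 9.6e-14, and adjusted p = 0.71 with an estimated correlation. Its median was 0.34 after the GC and length correction, 0.17 without YX968-NC replicate 1 and 0.1 with both changes (adjusted p = 1.1e-10, 6.2e-09 and 0.00011). With an estimated correlation 0 lists passed, and 1 by fry.

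YX26862 changed few genes by this test when all groups of a table shared the spread. With only the 2 groups in the fit far more were called at 6 h, as given below under processing. At 6 h the formin gene FHOD1 fell from 53.2 ± 3.53 to 34.7 ± 0.205 CPM (-0.62 ± 0.07, adjusted p = 0.041), the 1 gene called by edgeR; DESeq2 called 283, edgeR called 68 with no low-count filter, and 1561 genes had an unadjusted p under 0.05. Leaving out any DMSO or YX26862 library at 6 h ended the FHOD1 call (adjusted p up to 0.39), while leaving out YX968-NC replicate 1, which is in neither group but widens the shared estimate of spread, gave 1035 genes, most of them lower (772). At 24 h edgeR called 0 genes with YX26862 (2822 at an unadjusted p under 0.05, 6 by DESeq2, and 1 without DMSO replicate 2). With no low-count filter edgeR called 654 (317 higher, 337 lower). With YX968-NC at 24 h the 1 gene called was TSPAN13, a tetraspanin gene, up from 23.1 ± 0.359 to 30.8 ± 0.787 CPM (0.41 ± 0.06, adjusted p = 0.044), with 1689 genes at an unadjusted p under 0.05, 24 higher and 54 lower by DESeq2, and 283 with no low-count filter. The TSPAN13 call was lost without DMSO replicates 1 or 3 or any YX968-NC library, and the count was 504 without DMSO replicate 2 and 5 without DMSO replicate 3. Of 36 lists 3 passed with YX26862 at 6 h, 6 with YX26862 at 24 h and 5 with YX968-NC at 24 h, and 0 of any of them with an estimated correlation or by fry.

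The 3 compounds were then compared at the same dose and time. At 6 h YX968 exceeded YX968-NC in ABCA1 by 1.61 ± 0.26 (118 ± 13.3 against 38.3 ± 17.4 CPM, 95% interval 1.04 to 2.18, adjusted p = 0.021). It did so in BMF by 1.37 ± 0.13 (adjusted p = 0.0013), in the zinc finger gene ZNF608 by 1.14 ± 0.16 and in BCL3, an NF-kB cofactor gene, by 1.03 ± 0.11. Against YX26862 it was higher in BMF by 1.67 ± 0.13 (37.2 ± 0.538 against 11.7 ± 0.755 CPM, adjusted p = 0.00011), in ABCA1 by 1.57 ± 0.26 (interval 1 to 2.14, adjusted p = 0.011), in RRAD by 1.56 ± 0.21 and in ZNF608 by 1.29 ± 0.16. Lower with YX968 were SOX21 (-1.02 ± 0.19) and the cytokine gene TNFSF9 (-0.94 ± 0.16) against YX968-NC, and DDIT4L against YX26862 (-1.39 ± 0.16). MTATP6P1 and MTCO1P12 stood at -1.16 ± 0.19 and -1.1 ± 0.16 against YX968-NC. Against YX26862 they were at -1.31 ± 0.19 and -1.14 ± 0.16, with MTND2P28 at -1.09 ± 0.15. Of ABCA1 itself, YX26862 against DMSO gave 0.19 (interval -0.38 to 0.75) and YX968-NC gave 0.14 (-0.42 to 0.71), intervals that leave room for a change in either direction.

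At 6 h 106 genes differed between YX968 and YX968-NC (77 higher, 29 lower), 267 between YX968 and YX26862 (176 higher, 91 lower) and 0 between YX26862 and YX968-NC by edgeR (2132 at an unadjusted p under 0.05, 4 by DESeq2). With no low-count filter YX968 against YX968-NC had 942 genes, and YX26862 against YX968-NC had 42. With only the 2 groups in the fit YX968 against YX968-NC had 0 genes, while YX968 against YX26862 had many more than in the shared fit. DESeq2 split YX968 against YX968-NC as 362 to 279, library size alone as 39 to 36, and the YX26862 difference was 102 to 252 with library size alone and 464 to 367 after the GC and length correction. The YX968-NC difference was 637 without YX968-NC replicate 1, 3727 without its replicate 2, 34 without its replicate 3 and 17, 16 and 12 without YX968 replicates 1, 2 and 3. YX26862 against YX968-NC gave 3 without YX968-NC replicate 1 and 2879 without its replicate 2. For YX968 against YX26862 the count was 93, 97 and 77 without YX968 replicates 1, 2 and 3 and 83, 81 and 74 without the 3 YX26862 libraries in turn. Named genes of the YX968-NC difference other than BMF and BCL3 lost their calls without any 1 YX968 library or YX968-NC replicate 3 (adjusted p up to 0.53). BMF and BCL3 lost theirs only with the 2 groups fitted alone (adjusted p = 0.34 and 0.38). ABCA1 lost its call against YX26862 without YX968 replicates 2 or 3 or any YX26862 library (adjusted p up to 0.075).

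With the preset correlation, gene groups differed between YX968 and the other compounds at 6 h. Of 13 lists that passed against YX968-NC, 7 kept their call without YX968-NC replicate 1 and 0 with an estimated correlation. Without that library and with the GC and length correction 9 kept it, and 1 had the other direction. Against YX26862, 8 of 32 NF-kB and inflammatory genes were higher, with CSF1 at 0.82 ± 0.11 and IL6 at 0.73 ± 0.1; adjusted over the list alone 10 were higher and 2 lower. The NF-kB list had adjusted p = 7.5e-08, and adjusted p = 0.085 with an estimated correlation. Immediate early genes were higher in 8 of 29 cases, with DUSP1 at 0.89 ± 0.1, DUSP4 at 0.65 ± 0.06 and MYC at 0.59 ± 0.08; adjusted over the list alone 13 were higher and 4 lower. The immediate early list had adjusted p = 7.5e-08, and adjusted p = 0.1 with an estimated correlation. TBL1XR1 was the 1 NCoR/SMRT gene higher, by 1.13 ± 0.09, and 2 were adjusted over the list alone. The NCoR/SMRT list had adjusted p = 0.00042, and adjusted p = 0.062 with an estimated correlation. Against YX968-NC, 4 of 35 mesenchymal and matrix genes were higher, 5 adjusted over the list alone, with PLAU at 0.61 ± 0.06 and the integrin gene ITGA5 at 0.54. The mesenchymal list had adjusted p = 1.6e-08, and adjusted p = 0.41 with an estimated correlation. Fatty acid and lipid storage genes were higher than with YX968-NC in 3 of 29 cases, 7 adjusted over the list alone, with PDK4 at 0.76 ± 0.11 and PLIN2 at 0.49 ± 0.07. The fatty acid list had adjusted p = 2e-07, and adjusted p = 0.41 with an estimated correlation.

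At 24 h the differences were more precise. YX968 exceeded YX968-NC in ABCA1 by 1.87 ± 0.1 (22.5 ± 1.18 against 6.15 ± 0.52 CPM, interval 1.67 to 2.08, adjusted p = 3.5e-08), ZMIZ1-AS1 by 1.74 ± 0.19, SCNN1A by 1.61 ± 0.18 and DHRS3 by 1.43 ± 0.16. It exceeded YX26862 in ABCA1 by 1.55 ± 0.09 (interval 1.35 to 1.75, adjusted p = 5.2e-07), SCNN1A by 1.42 ± 0.17, PTPRH by 1.37 ± 0.15 and the natural killer receptor gene KLRC2 by 1.3 ± 0.18. LINC00707 was lower with YX968 than with YX968-NC (-1.29 ± 0.1) and than with YX26862 (2.96 ± 0.251 against 7.52 ± 0.478 CPM, -1.34 ± 0.1). Also lower were the endothelial secreted protein gene ESM1 (-1.01 ± 0.07), SOX21 (-0.99 ± 0.13) and C15orf48 (-0.91 ± 0.18) against YX968-NC, and the prolactin receptor gene PRLR (-1.1 ± 0.2), GPR17 (-1.06 ± 0.1) and PLCH2 (-1.15 ± 0.24) against YX26862. Between YX26862 and YX968-NC, FAM229A (0.92 ± 0.18), LTB4R2 (0.83 ± 0.16), L3MBTL1 (0.83 ± 0.16) and PINLYP (0.82 ± 0.12) were higher. SNX32 (-1.29 ± 0.26), PRMT5-AS1 (-0.81 ± 0.18) and SMCO4 (-0.77 ± 0.17) were lower, and the antisense and overlapping genes among these are uncertain. For ABCA1 the changes against DMSO were 0.23 with YX26862 (interval 0 to 0.45) and -0.09 with YX968-NC (-0.32 to 0.14), and for BMF they were 0.02 (-0.27 to 0.32) with YX26862.

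In numbers, 2694 genes differed between YX968 and YX968-NC at 24 h (1535 higher, 1159 lower), 718 between YX968 and YX26862 (362 higher, 356 lower) and 205 between YX26862 and YX968-NC (125 higher, 80 lower). Library size alone split the first pair of counts as 1177 to 1715 and 226 to 653. Against YX968-NC the YX968 count was 1475 and 1262 without YX968 replicates 2 and 3 and 1794, 1429 and 1748 without YX968-NC replicates 1, 2 and 3. Against YX26862 it was 368, 322 and 380 without the 3 YX968 libraries in turn and 301, 385 and 392 without the 3 YX26862 libraries. With no low-count filter YX26862 against YX968-NC had 1518 genes. With the filter it gave 1, 3 and 12 genes without YX968-NC replicates 1, 2 and 3 and 0 and 3 without YX26862 replicates 1 and 3. Its named genes lost their calls without each of these libraries (adjusted p up to 0.19), except PINLYP without YX968-NC replicate 3, and SNX32, PRMT5-AS1 and SMCO4 also lost theirs without YX26862 replicate 2. PLCH2 lost its call against YX26862 without replicates 1 or 3 of either group (adjusted p up to 0.064). DMSO replicate 2, which stood apart from its group at 24 h, enters these fits only through the shared spread, and leaving it out gave 4563, 1782 and 2527 genes.

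Lists between compounds at 24 h included the 3 that also passed with an estimated correlation. YX968 was above YX26862 in 10 of 30 hypoxia-inducible genes, 16 adjusted over the list alone, with ANGPTL4, a lipase inhibitor gene, at 0.66 ± 0.06 and VEGFA at 0.33 ± 0.05. The hypoxia list had adjusted p = 4.6e-10, and adjusted p = 0.039 with an estimated correlation. Of 29 fatty acid and lipid storage genes 9 were higher and 1 lower, 12 and 2 adjusted over the list alone, with SCD at 0.85 ± 0.07 and PLIN2 at 0.39 ± 0.04. The fatty acid list had adjusted p = 3e-08, and adjusted p = 0.039 with an estimated correlation. Of 7 NCoR/SMRT genes 2 were higher, 3 adjusted over the list alone, TBL1XR1 by 0.64 ± 0.05 and TBL1X by 0.22 ± 0.05. The NCoR/SMRT list had adjusted p = 9.6e-06, and adjusted p = 0.04 with an estimated correlation. Against YX968-NC, 4 of 7 NCoR/SMRT genes were higher, including NCOR1 (0.31 ± 0.07), a corepressor gene; adjusted over the list alone 4 were higher and 1 lower. The NCoR/SMRT list had adjusted p = 0.0013, and adjusted p = 0.22 with an estimated correlation. Polyadenylated histone genes were lower than with YX968-NC in 8 of 15 cases, 9 adjusted over the list alone. The histone list had adjusted p = 0.0013, and adjusted p = 0.42 with an estimated correlation. YX26862 was below YX968-NC in 2 of 28 immediate early genes, IER5 (-0.26 ± 0.05) and DUSP1 (-0.25 ± 0.05), 9 adjusted over the list alone. The immediate early list had adjusted p = 2.2e-05, and adjusted p = 0.6 with an estimated correlation.

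The YX968 changes at 6 h and 24 h overlapped in part. Of genes tested at both times 96 were higher at both, where independent lists of those sizes would share 12. Lower at both were 45, where 24.8 would be shared. Another 11 moved in opposite directions, for which no expected number was computed. Across genes, which are not independent replicates, the log2 changes correlated at 0.136 (Pearson, with -0.0032 in simulated unchanged groups). Leaving out single libraries gave 0.087 (without YX968 replicate 1 at 24 h) to 0.173. ABCA1, BMF and TBL1XR1 were higher and SOX21 lower at both times. Between compounds at one time the DMSO libraries were shared. At 6 h YX968 and YX968-NC correlated at 0.493 where simulated unchanged groups gave 0.486, with a covariance of 0.0551 against 0.0247. YX968 and YX26862 correlated at 0.549 against 0.496, with a covariance of 0.0436 against 0.0246, and YX968-NC and YX26862 at 0.557 against 0.482, with a covariance of 0.0537 against 0.0249. At 24 h YX968 and YX968-NC correlated at 0.259 against 0.495 simulated, with a covariance of 0.0137 against 0.0146, and YX968 and YX26862 at 0.503 against 0.501, with a covariance of 0.0279 against 0.0146. YX968-NC and YX26862 correlated at 0.292 against 0.497, with a covariance of 0.0134 against 0.0145. Without DMSO replicate 3 at 24 h YX968-NC correlated at 0.42 with YX968 and at 0.46 with YX26862, and no simulation was run for those libraries. Without YX968-NC replicate 1 the 6 h values for YX968 and YX968-NC were 0.564 against 0.45, and without DMSO replicate 2 the 24 h values for YX968 and YX26862 were 0.495 against 0.599. With 3 DMSO libraries the controls could not be split, so part of any excess may come from them. The simulated DMSO libraries were drawn anew, so a shift that many genes shared in the real ones is missing from the simulated values.

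UF010 at 10 µM and YX968 at 50 nM, both for 24 h, were measured in separate tables with their own DMSO libraries, and their doses differed. BMF rose with either (1.23 ± 0.1 with UF010, 1.25 ± 0.12 with YX968), and so did ABCA1 (1.16 ± 0.13 and 1.78 ± 0.1) and ARNTL (0.8 ± 0.07 and 0.77 ± 0.07, a gene picked after its values were seen), while SOX21 was lower with either (-0.69 ± 0.15 and -0.93 ± 0.13). PLK1 changed by -2.87 ± 0.08 with UF010 and by 0 ± 0.04 with YX968 (95% interval -0.09 to 0.09). Of the genes tested in both, 386 were higher with both compounds and 518 lower with both, where independent lists would share 308 and 397. Another 604 moved in opposite directions. No expected number was computed for these, so this count alone shows no disagreement. The correlation of log2 changes across genes was 0.067 (-0.00635 in simulated unchanged groups). With single libraries left out it ran from 0.033 (without YX968 replicate 1) to 0.089. It was higher between UF010 and the negative control YX968-NC at 24 h, at 0.261 (-0.00505 simulated), and 0.087 between UF010 and YX26862 (-0.00045 simulated), so the likeness across all genes was not particular to YX968.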

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

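The counts over other splits of the libraries were chosen only after the result was seen. So were the tests of length trend and depth for the library that stood apart. The GC and length correction and the fits without the libraries in doubt were also chosen only then. Tests below that rest on either, such as those of genes lower with every compound and of lists matched on level, were therefore not set beforehand. The remaining tests below were.

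Effects differed between compounds and between times. A test of the difference called 8837 of 15496 genes between the UF010 effect and the YX968 effect at 24 h (4500 higher, 4337 lower with UF010; library size alone gave 5422 and 3157, with the median moved by 0.151). Mitosis genes differed by a median of -1.98 (adjusted p = 0.00016 with an estimated correlation), DNA replication genes by -1.21 (0.0061), SIN3, NuRD and CoREST genes by -0.53 (0.0061), neuronal genes by 2.14 (0.00059), epithelial genes by 1.43 (0.026) and basal and myoepithelial markers by 2.22 (0.01), and these 6 lists were the ones that passed with an estimated correlation. Dose and table differed along with the compound, so these cannot be told apart. Members silent in every group were not tested here either, which can tilt the neuronal, epithelial and basal medians upward. Between 24 h and 6 h the effect differed in 541 genes for YX968 (330 higher, 211 lower; 593 and 109 with library size alone), 43 for YX26862 (40 higher, 3 lower) and 144 for YX968-NC (116 higher, 28 lower; 389 and 280 by DESeq2, 241 and 165 after the GC and length correction). Time and count table are confounded here and cannot be told apart. The YX968 count was 336, 324, 306 and 350 without DMSO replicate 3 or YX968 replicate 3 at 6 h or YX968 replicates 2 or 3 at 24 h. For YX26862 it was 12 without DMSO replicate 3 at 6 h, 12, 21 and 18 without its 6 h libraries in turn, 25, 75 and 18 without the DMSO 24 h libraries in turn, and 13 and 12 without its 24 h replicates 1 and 3. For YX968-NC it was 43 and 35 without DMSO replicates 1 and 3 at 6 h, 4108 and 1869 without its 6 h replicates 2 and 3, 78, 64 and 59 without the DMSO 24 h libraries in turn, and 56, 33 and 56 without its 24 h libraries in turn.

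Other splits of the same libraries were run for each count. For the comparisons of 3 against 3 there are 10 splits, too few for a share under 0.05. The real count was as large or larger than in all others, so that 1 split of 10 reached it, for UF010 (12399, highest other 0), YX968 at 6 h (608, 0) and 24 h (1951, 0), YX968-NC at 6 h (71, 0) and 24 h (1, 0), YX26862 at 6 h (1, 0), YX968 against YX968-NC at 6 h (106, 0) and 24 h (2694, 0), YX968 against YX26862 at 6 h (267, highest other 1) and 24 h (718, 0) and YX26862 against YX968-NC at 24 h (205, 0). For YX26862 at 24 h and YX26862 against YX968-NC at 6 h, with 0 genes called, all 10 splits gave as many. For the tests of whether effects differ, 40 splits were drawn each, with either effect split on its own, so that a drawn split can leave the larger effect whole. As many genes as in the real grouping were called in 3 of 40 splits, the real one included, for UF010 against YX968 (8837, highest other 8867), in 2 for the YX968 times (541, 556) and in 2 for the YX26862 times (43, 205). All other splits that reached these counts left an effect whole, and the highest count with both effects regrouped was 0, so the splits decide nothing about chance here. For the YX968-NC times 6 splits of 40 reached the real count, the real one included (144, highest other 1922). Of the others that reached it, 4 left an effect whole, which decides nothing. Among the 26 splits that regrouped both effects, 1 reached it, and because of that split chance was not excluded. The split with 1922 genes regrouped both effects and called several times the real count, and the cause of this was not tested.

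The library YX968-NC replicate 1 at 6 h stood apart from its group. Replicate 2 thinned to the same total gave a chi-square per degree of freedom of 11.6 against replicate 3, and 14.9 at full depth. Thinning can hardly raise this measure, so it could not have reached the 132 and 79.3 of this library. These values argue against fewer reads alone as the cause of the gap. They do not address other properties of a library with a low total. A YX968 library under this label is argued against. The deviation of replicate 1 had a slope of -0.194 (SE 0.035, 2249 genes) on the YX968 difference, where a value near 1 was needed. GC content and transcript length accounted for 30.2% of the variance of its deviation across genes, where the highest of the other 11 libraries of the table had 32.9%. A length and GC trend may therefore account for part of the gap, and no biological explanation was tested.

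Without that library, 311 genes were lower in all 3 compounds than in DMSO at 6 h, such as HNRNPH1, a splicing regulator gene (-0.15 with YX968, -0.16 with YX968-NC, -0.23 with YX26862), LENG8 (-0.69, -0.7, -0.76) and NEAT1 (-0.59, -0.55, -0.73), picked after their values were seen; with it there was 1. In the other direction 41 genes were higher in all 3 without that library (0.05 on average in simulated unchanged groups) and 0 with it. For the lower genes, simulated unchanged groups gave 0 on average. With no gene changed, adjusted p-values let almost none pass, so this value and the 0.05 above were nearly fixed beforehand. They therefore decide nothing about chance in the shared DMSO libraries. The simulation also drew those libraries anew and each gene on its own, so it cannot decide about shifts that many genes share in the real ones. The 311 lower genes were richer in GC (median 58.9 against 48 percent), but a GC and length trend as the whole cause is argued against, since 187 of the 284 with both properties, 65.8%, were still lower in all 3 after the correction, with medians going from -0.47, -0.44 and -0.44 to -0.43, -0.33 and -0.32. A response shared by the 3 compounds stays open: at 24 h the same genes had medians of 0.02, -0.14 and 0.04 with YX968, YX968-NC and YX26862, and a response could have ended by then. A difference in how the 3 DMSO libraries at 6 h were handled was not tested and stays open too.

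Genes called higher by YX968 at 24 h were also slightly higher with the other compounds at 6 h, by medians of 0.055 with YX968-NC and 0.047 with YX26862. After the GC and length correction these became 0.032 and -0.006, against 95% ranges of 0.021 to 0.035 and 0 to 0.013 in 10000 lists matched on level. For YX968-NC 89.87% of matched lists lay below its median, which is inside the range, so a partial response was neither shown nor excluded. For YX26862 0.01% lay below, so after the correction these genes showed no rise as a set. The correction also moved genes called lower past their range on the other side, as given below, and the matched lists treat genes as independent. A partial response to YX26862 was therefore neither shown nor excluded. A length and GC trend may account for the uncorrected values. In YX968 itself at 6 h the median was 0.119 after the correction, above its range of 0.029 to 0.047. Genes called lower by YX968 at 24 h had medians of -0.024 with YX968-NC and -0.041 with YX26862 at 6 h. After the correction these turned to 0.032 and 0.022, above their ranges of 0.002 to 0.02 and -0.008 to 0.006. In YX968 itself their median was -0.013 as fitted, below its range of 0.011 to 0.034. After the correction it was -0.003, inside its range of -0.012 to 0.01. As a set these genes thus gave no clear fall at 6 h against which a partial one could be read. Even so, 45 genes were called lower with YX968 at both times.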

How the results depend on the processing

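The GC and length correction and the fits without the libraries in doubt were chosen only after the result was seen; every other setting was planned. No paired analysis was possible because replicate numbers were given in accession order and only name libraries. No named gene changed direction: of 107 named gene results 70 kept their call under every setting, and over the planned settings 1168 of 1369 values kept it and 201 no longer passed, over the added ones 274 of 276 kept it. The UF010 count stayed within 1.5 times in every setting except the fold threshold, and from 11681 to 13194 when libraries of either group were left out. Counts with few or no calls depend on the shared spread at 6 h, which fell from a common dispersion of 0.0149 to 0.00304 without YX968-NC replicate 1; for other settings the cause was not tested. Small changes are missed in part: of genes simulated as changed 1.5 fold by YX968, 46.3% were recovered at 6 h and 74.6% at 24 h, with common dispersions of 0.0149 and 0.00302, and no test separated spread from depth.

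Requiring an absolute log2 change of at least 1 left 4455 genes for UF010; 91, 12 and 0 for YX968, YX968-NC and YX26862 at 6 h; 42 and 0 for YX968 and YX968-NC at 24 h; 11 and 23 for YX968 against YX968-NC and YX26862 at 6 h, and 94 and 27 at 24 h, with 22 for YX26862 against YX968-NC; and 3497, 74, 6 and 8 for the differences of effects (UF010 against YX968, then 24 h against 6 h for YX968, YX26862 and YX968-NC). At an adjusted p under 0.01 the counts were 134, 0 and 0 for YX968, YX968-NC and YX26862 at 6 h and 17 and 88 for YX968 against YX968-NC and YX26862; at 24 h 490 and 0 for YX968 and YX968-NC, and 1026, 276 and 6 for YX968 against YX968-NC, YX968 against YX26862 and YX26862 against YX968-NC; and 221, 10 and 22 for the time differences.

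DESeq2 gave 1102, 1288 and 283 genes for YX968, YX968-NC and YX26862 at 6 h, 641, 736 and 4 for YX968 against YX968-NC, YX968 against YX26862 and YX26862 against YX968-NC, 78 and 6 for YX968-NC and YX26862 at 24 h, 489 for YX26862 against YX968-NC at 24 h, and 921, 161 and 669 for the time differences; HDAC8 then passed in the YX968-NC time difference (-0.59, adjusted p = 0.027). Library size alone gave 995 and 157 for YX968 and YX968-NC at 6 h, 0 for YX968-NC at 24 h, 26 for the YX26862 time difference, 0.26 and -0.1 for HDAC3 and HDAC8 with UF010 and 0.3 for HDAC3 in the UF010 against YX968 difference (adjusted p = 0.0041). With no low-count filter there were 1578 and 68 genes for YX968-NC and YX26862 at 6 h, 942 and 42 for YX968 and YX26862 against YX968-NC at 6 h, 283 and 654 for YX968-NC and YX26862 at 24 h, 1518 for YX26862 against YX968-NC at 24 h and 308, 27 and 65 for the time differences. A stricter filter gave 178 and 26 for YX968-NC and YX26862 at 6 h. With only the 2 groups in the fit the counts were 3151, 0 and 2079 for YX968, YX968-NC and YX26862 at 6 h, 0 and 4124 for YX968 against YX968-NC and YX26862, 335 and 0 for YX968 and YX968-NC at 24 h, and 4176, 1524 and 2294 for YX968 against YX968-NC, YX968 against YX26862 and YX26862 against YX968-NC; with only the 4 groups of a time difference they were 1093, 159 and 0.

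After the GC and length correction there were 1589, 250 and 57 genes for YX968, YX968-NC and YX26862 at 6 h, 333, 831 and 1 for YX968 against YX968-NC, YX968 against YX26862 and YX26862 against YX968-NC, 194 for YX968-NC at 24 h (99 higher, 95 lower), 1783 and 707 for YX968 against YX26862 and YX26862 against YX968-NC at 24 h, and 1361, 205 and 406 for the time differences; HDAC3 passed with UF010 (0.12, adjusted p = 0.015). Without the libraries in doubt the counts were 3082, 853 and 1035 at 6 h, 637, 2252 and 3 between compounds, 504 and 1 for YX968-NC and YX26862 at 24 h, 4563, 1782 and 2527 between compounds at 24 h and 1234 and 315 for the YX968 and YX26862 time differences. Doing both gave 4472, 1096 and 1164 at 6 h, 1227, 3335 and 40 between compounds, 668 and 6 for YX968-NC and YX26862 at 24 h, 4641, 2788 and 2091 between compounds at 24 h and 2526, 560 and 244 for the time differences.

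Leaving out 1 library of the groups compared at a time (a library of another group in the same fit can move the counts further, as given above for the libraries in doubt) gave 123 to 273 genes for YX968, 0 to 4416 for YX968-NC and 0 for YX26862 at 6 h, where the highest YX968-NC value was without its replicate 2; 12 to 3727, 74 to 97 and 0 to 2879 for YX968 against YX968-NC, YX968 against YX26862 and YX26862 against YX968-NC at 6 h, the first and last highest without the same library; 528 to 2841, 0 to 504 and 0 to 1 for YX968, YX968-NC and YX26862 at 24 h; 1262 to 2283, 301 to 392 and 0 to 158 for the compound differences at 24 h; and 306 to 536, 12 to 75 and 33 to 4108 for the time differences. HDAC3 with UF010 ran from 0.06 to 0.17, and HDAC8 from 0.27 to 0.67 with YX968-NC at 6 h, from -0.57 to -0.17 and -0.48 to -0.08 in YX968 and YX26862 against it, and from -0.78 to -0.37 in its time difference, where it also passed without YX968-NC replicate 3 at 6 h (-0.64, adjusted p = 0.031). The lists passing ran from 5 to 11 for YX968, 1 to 4 for YX26862 and 3 to 9 for YX26862 against YX968-NC at 6 h, 0 to 7 for YX968-NC at 24 h, and 5 to 9, 3 to 9 and 4 to 9 for the time differences.

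An estimated correlation left 3 lists for YX968 against YX26862 at 24 h, 6 for UF010 against YX968 and 0 in every other comparison. By fry the lists numbered 34 for UF010, 1 and 0 for YX968-NC and YX26862 at 6 h, 0 for YX26862 against YX968-NC at 6 h, 0 for YX968-NC and YX26862 at 24 h, 14 and 2 for YX968 and YX26862 against YX968-NC at 24 h, 30 for UF010 against YX968 and 9, 0 and 2 for the time differences. Lists numbered 5 and 3 for YX26862 against DMSO and YX968-NC at 6 h after the correction, 9 for the YX968 time difference with library size alone and without the libraries in doubt, and, with both changes, 7 and 9 for YX26862 against DMSO and YX968-NC at 6 h, 8 and 1 for YX968-NC and YX26862 at 24 h and 9 for the YX968 time difference. Over genes of at least 10 CPM the correlation was 0.434 for YX968 and YX26862 at 6 h, 0.266 and 0.171 for 6 h and 24 h of YX968 and YX26862, -0.038 and 0.016 for UF010 with YX968 and YX26862 at 6 h, and 0.124 and 0.321 for UF010 with YX968 and YX968-NC at 24 h.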

Other observations

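The tests of this part were all planned. Other lists were examined with UF010. Among markers of luminal breast epithelium 9 of 14 rose and 3 fell, with AGR2 at 2.54 and the pioneer factor gene FOXA1 at 2.29 up and XBP1 at -1.01 (list adjusted p = 0.18), and of 8 endothelial markers 6 rose and 1 fell, with VWF at 3.93 and KDR at 1.17 (adjusted p = 0.16). Of 6 germline genes 4 rose and 0 fell, including TEX14 at 2.33 and PIWIL2 at 2.07 (adjusted p = 0.16). Counts adjusted over the list alone were the same for these lists. The low-count filter can tilt them toward rises, as said for the other marker lists. Heat shock genes rose in 2 and fell in 11 of 16 cases, 3 and 11 adjusted over the list alone, and the small heat shock protein gene HSPB8 (4.51 ± 0.13) went against the chaperonin gene HSPD1 (-0.92 ± 0.04) and HSPA8 (-0.84; adjusted p = 0.14). Of 28 ubiquitin ligase and proteasome genes 22 fell and 1 rose, with a median of -0.38, the same adjusted over the list alone (adjusted p = 0.0032, and adjusted p = 0.44 with an estimated correlation). Histone acetyltransferase and bromodomain genes fell in 20 and rose in 2 of 25 cases, with a median of -0.6, again the same adjusted over the list alone (adjusted p = 0.00044, and adjusted p = 0.44 with an estimated correlation).

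With YX968 at 24 h the cohesin genes SMC3 (0.24), STAG2 (0.28) and SMC1A (0.23) rose, 3 of 14, while adjusted over the list alone 11 rose and 1 fell (adjusted p = 0.0017, and adjusted p = 0.64 with an estimated correlation). Apoptosis regulators went both ways: 6 of 32 rose, including the decoy receptor gene TNFRSF10D (0.39) and BCL2L11 (0.36), and 4 fell, including BOK (-0.53); adjusted over the list alone 8 rose and 8 fell (list adjusted p = 0.76). Of 11 deacetylase genes HDAC5 rose (0.34 ± 0.07) and HDAC11 fell (-0.38 ± 0.1), with HDAC3 and HDAC8 not called (list adjusted p = 0.63). In 42 interferon-stimulated genes 0 rose and 4 fell by edgeR, IFI44 by -0.31 among them (list adjusted p = 0.28).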
